A study of Mus musculus with 6 samples.

How the data were processed

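The data are RNA-seq libraries of mouse CD8+ T cells, 6 in all, each with a column in a table of 18122 rows that the authors deposited in FPKM, fragments per kilobase of gene, scaled to the number of mapped fragments. Per the submitters' processing notes, HISAT2 2.0.5 was used and the builds mm39 and hg38 are named without a role. The read counter, the annotation and the rule of the filter on missing values that the file is named for are not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and libraries were prepared with Illumina protocols. The description field of the labels also names 10X Genomics, and the treatment text names mice with floxed Rpa1. The values are bulk values per library and not per cell. Genotype and CD44 fraction were taken from the sample titles, and every column of the table matched a title, so 0 columns were left unused.

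Gene symbols were used as the table gives them. Of these, 18100 (99.9%) were found in a RefSeq gene table of assembly GRCm38.p6, which is not the build of the processing notes and was used only for names, gene types and chromosomes. No coordinates are given for that reason. In the table, 17 symbols had more than 1 row (37 rows in all). FPKM values of a gene across libraries are whole multiples of what 1 read is worth, so whole reads were recovered by searching for the smallest common step. All of the 16220 rows above 0 in 2 or more libraries (100%) came out whole within a tolerance of 1e-06 reads, against 0% of 2000 rows perturbed as a control. The 1902 rows above 0 in 1 library were taken as 1 read. A common factor of all values of a gene is not seen by this search, so recovered reads are the smallest numbers that fit. Gene lengths were taken from the same recovery and carry the same uncertainty in genes with few reads.

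Recovered reads came to 23490008 in the Dusp2KO CD44lo library and to between 42816073 and 55830235 in the others. They gave depths, the floor of 3 reads and the alternatives that need reads, and did not enter the main test. FPKM totals ran from 301211 to 332997 and were not scaled further in the main test. Floors cover counting error only.

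The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, for the 9691 genes with a mean of at least 1 FPKM over the 6 libraries, with a variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided. A model with 1 coefficient per group (2 residual degrees of freedom, from the CD44hi pairs) gave Dusp2KO against WT in CD44hi, CD44hi against CD44lo within each genotype, and the interaction. An additive model of genotype and fraction (3 residual degrees of freedom) gave both main effects. In the CD44lo fraction alone, with 1 library per genotype, differences were described without a test. The fixed filter, the models, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

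The 20 gene lists were virtual memory and CD8 memory, effector and cytotoxic, naive and quiescence, type I interferon response, IL-4 and STAT6 response, immediate TCR-induced genes, ERK feedback and MAP kinase phosphatases, inhibitory receptors, TNF receptor family and costimulation, common gamma chain and STAT5, S phase, G2 and M phase, glycolysis, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis, amino acid transport and ATF4 targets, unfolded protein response, p53 targets and apoptosis, and chemokine receptors and trafficking. Some genes, such as Lta and Ccl5, are in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Markers of other cell types and of RNA quality were tabulated, and 6 marker sets with enough tested genes were tested the same way and adjusted over those 6.

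The genes named per comparison are the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 5 FPKM, no overlap between the sides (within each genotype or fraction for the adjusted comparisons), and a symbol that is not a predicted gene, plus Dusp2, Rpa1, Cd44 and up to 4 members per list with the smallest p. For the interaction, 5 and 5 were taken without the overlap condition. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, median-ratio scaling, quantile normalization, rescaling to a total of 1000000, fits without the trend and with robust variance, a replicate block, each library left out in turn, other model forms, and other scalings of the list tests. Chosen after seeing the data were limma voom on recovered reads, removal of a loess trend (span 0.5) on gene length from each library, thinning of reads to the shallowest library, and leaving out chromosome 14.

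Each test was tried on simulated data drawn from the real means and spreads with 200 of 9691 genes changed by 0.5, 1 or 2 log2 units. For Dusp2KO against WT in CD44hi it recovered 0%, 83.0% and 98.0% of the changed genes, for CD44hi against CD44lo adjusted for genotype 64.5%, 91.5% and 99.5%, and for Dusp2KO against WT adjusted for fraction 67.5%, 91.0% and 98.5%. For CD44hi against CD44lo it recovered 0%, 67.0% and 94.5% in WT and 0%, 57.0% and 92.5% in Dusp2KO, and for the interaction 0%, 37.5% and 88.5%. A change of 0.5 in so few genes thus went undetected with 2 residual degrees of freedom. The spread came from the model with 1 coefficient per group. For the additive tests no interaction was simulated, so their recovery may be overstated. The recovery of reads gave back 100% of 2881 simulated genes. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.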

Results

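RNA was sequenced from CD8+ T cells of wild-type (WT) mice and of mice lacking Dusp2 (Dusp2KO), whose product is a phosphatase that removes phosphate from MAP kinases. The cells came from lymph nodes and were cultured for 18 h on plate-bound anti-CD3 antibody at 1 µg/mL with anti-CD28 antibody at 1 µg/mL, IFN-α at 50 ng/mL and IL-4 at 20 ng/mL. Per the labels, this mixture was meant to induce virtual memory T cells, which carry a memory phenotype without having met their antigen. Cells were then sorted by the surface glycoprotein CD44 into a very high fraction (CD44hi) and a low fraction (CD44lo). The CD44hi fraction had 2 libraries per genotype. The CD44lo fraction had 1 library per genotype and so no replicates.

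Reads recovered from the FPKM values (fragments per kilobase of gene, scaled to sequencing depth) numbered 55782810 and 52077365 in the Dusp2KO CD44hi libraries and 42816073 and 55830235 in the WT CD44hi libraries. The Dusp2KO CD44lo library was the shallowest with 23490008, and the WT CD44lo library had 50084878. The labels do not say whether libraries came from separate animals or cultures, so p-values measure only the spread between these samples. Set against counting error alone, with reads taken as independent molecules, the chi-square per degree of freedom was 7.14 between the Dusp2KO and 33.0 between the WT CD44hi libraries, so the WT pair differed more. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 9691 genes tested, and means are given ± SD with n = 2.

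Dusp2 was measured at 82.6 and 83.9 FPKM in the WT CD44hi libraries and at 116 FPKM in the WT CD44lo library. It was at 0 and 0.0283 FPKM in the Dusp2KO CD44hi libraries, that is 0 and 3 reads, and at 0 FPKM in the Dusp2KO CD44lo library. The floor of 3 reads stands at 0.0264, 0.0283 and 0.0627 FPKM in these 3 libraries and covers counting error only. Part of the labels names mice with a T cell deletion of Rpa1, a subunit of the DNA-binding replication protein A, in place of Dusp2 knockout mice. Rpa1 was at 41.3 and 41.4 FPKM in Dusp2KO CD44hi, 33.7 and 35.2 FPKM in WT CD44hi, 28.2 FPKM in Dusp2KO CD44lo and 27.4 FPKM in WT CD44lo. The values of both genes thus follow a Dusp2 knockout. Cd44 followed the sort, at 79.9 and 65.3 FPKM in WT CD44hi, 65.4 and 66.3 FPKM in Dusp2KO CD44hi, and 1.43 and 1.33 FPKM in the WT and Dusp2KO CD44lo libraries. Cd8a stood between 246 and 358 FPKM, while Cd4 reached no more than 0.0228 FPKM in any library.

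**Figure D1:**
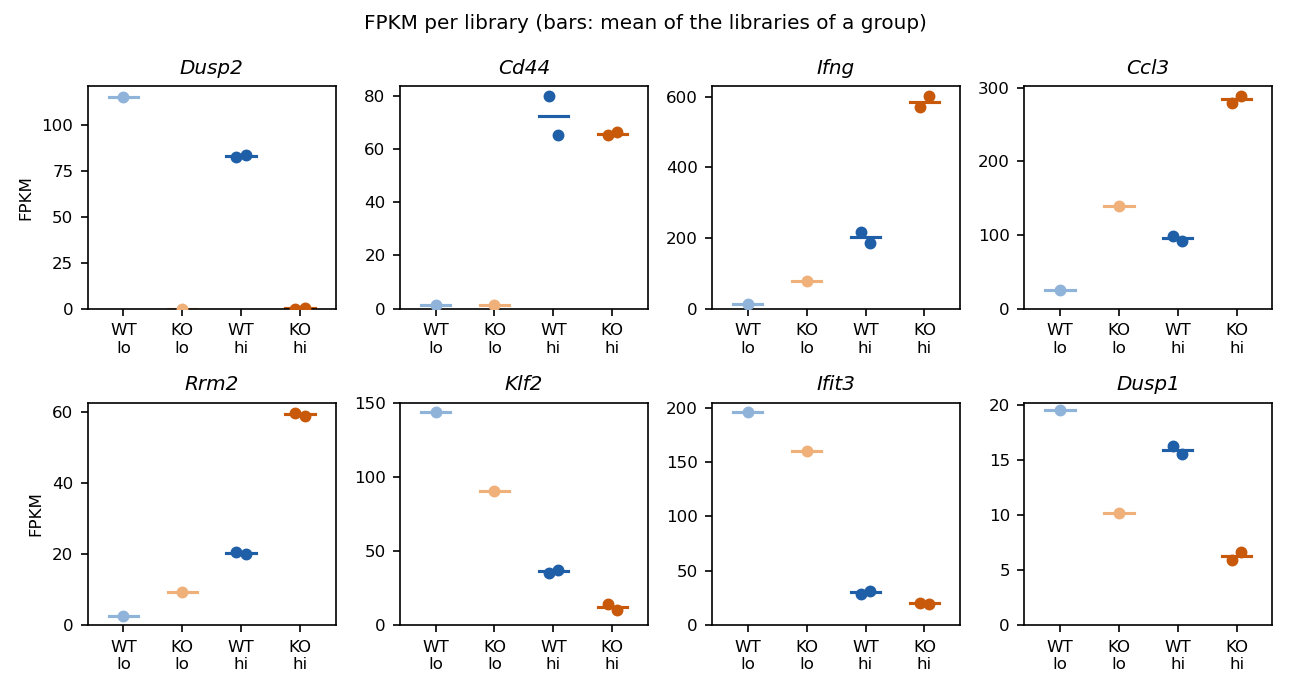
FPKM (vertical axes, linear, starting at 0) of 8 genes in each library, with a point per library and a bar at the group mean, for the CD44lo (lo, 1 library per genotype) and CD44hi (hi, 2 libraries per genotype) fractions of WT and Dusp2KO (KO) cells. Ifng averaged 586 FPKM in Dusp2KO CD44hi and 202 FPKM in WT CD44hi, and Dusp2 was at or near 0 in the 3 Dusp2KO libraries.

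The genotype difference in CD44hi cells was read from 2 Dusp2KO against 2 WT libraries. Other differences between the mice of each genotype, such as possible ones in sex or strain, were not separated from it. Some cytokine and chemokine genes were higher in Dusp2KO. Ifng, the gene of interferon-γ, rose from 202 ± 22.1 to 586 ± 21.4 FPKM (log2 fold change 1.54, SE 0.091, adjusted p = 0.00064). Ccl3, a chemokine that attracts other leukocytes, rose from 95.4 ± 4.49 to 284 ± 7.01 FPKM (log2 fold change 1.56, SE 0.069, adjusted p = 0.00015), and the related Ccl4 and the cytokine Lta rose by 1.25 and 1.30 log2 units. Rrm2, a subunit of the ribonucleotide reductase that makes DNA precursors, rose from 20.2 ± 0.366 to 59.4 ± 0.703 FPKM (log2 fold change 1.51, SE 0.062, adjusted p = 0.00013). The proliferation marker Mki67 and the mitotic kinase Pbk rose by 1.35 and 1.32.

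Apart from Dusp2 itself, whose log2 fold change of -6.38 is set by the pseudocount, the largest fall among the named genes was that of Lgals3, the gene of galectin-3. It went from 58.2 ± 2.79 to 3.16 ± 0.367 FPKM (log2 fold change -3.83, SE 0.088, adjusted p = 5.3e-06). Ifi208, a member of the interferon-inducible Ifi200 family, changed by -3.10, and Klf2, a transcription factor of quiescent T cells, by -1.52. Psmb5, a catalytic subunit of the proteasome, changed by -1.42, Itm2a by -1.38, Tmem254a by -1.79, and the MAP kinase phosphatase gene Dusp1 by -1.22. Lgals3, Tmem254a, Psmb5, Pbk and the early TCR response gene Egr3 lie on chromosome 14 by the RefSeq table of assembly GRCm38.p6, where 43 of the 97 genes with a 2-fold or larger difference lie, while Dusp2 lies on chromosome 2. T cell receptor alpha segments on that chromosome were among the largest differences in both directions, with Trav8d-1 at 2.21 and Trav16d-dv11 at 1.43, and Trav12-2 at -3.53 and Trav16 at -2.45. These segments have near-identical copies that can share reads, so their values are uncertain. Xist, the RNA that coats the inactive X chromosome of female cells, had the largest rise of the named genes, with 4.02. It was at 15.1 and 15.5 FPKM in the Dusp2KO CD44hi libraries, at no more than 5 reads in each WT library and at 0 in the Dusp2KO CD44lo library.

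In all, 2586 of the 9691 genes passed the threshold, 1248 higher and 1338 lower in Dusp2KO, and 97 of them differed 2-fold or more (48 higher, 49 lower). With each library rescaled to a total of 1000000 the split was 1292 higher and 914 lower. The count was 1185 without Dusp2KO CD44hi replicate 1, 1088 without Dusp2KO CD44hi replicate 2, 4092 without WT CD44hi replicate 1, and 2 with no filter on low values. Differences correlated with gene length across genes (Spearman rho = 0.27), as did those between the WT CD44hi libraries (Spearman rho = 0.32).

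Cell cycle genes rose together in Dusp2KO CD44hi cells. Of the 33 measured genes of S phase and DNA replication, 25 rose and 8 did not pass (28 rose when adjusted over the list alone; camera adjusted p = 3.8e-15, adjusted p = 0.338 with an estimated correlation). The examples were Clspn (0.99), a checkpoint protein of replication forks, Mcm10 (0.84), a replication initiation factor, and Uhrf1 (0.72), which maintains DNA methylation. Of 21 genes of G2 and M phase, 14 rose and 1 fell, and these counts were 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.9e-07, adjusted p = 0.494 with an estimated correlation). Topoisomerase gene Top2a was at 0.97, the spindle motor Kif11 at 0.90 and the mitotic cyclin Ccna2 at 0.77. Of 27 ribosome biogenesis genes 8 rose and 1 fell, 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00025, adjusted p = 0.462 with an estimated correlation), with the nucleolar proteins Dkc1 at 0.46 and Ncl at 0.45.

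Effector and T cell receptor (TCR) response genes also moved. Of 18 effector and cytotoxic genes 12 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.581 with an estimated correlation). Of 25 genes induced early by TCR signals, 12 rose and 4 fell, 13 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.494 with an estimated correlation). Among them were the transcription factors Batf3 (1.45), Egr3 on chromosome 14 (1.10), Nr4a1 (0.98) and Nr4a3 (0.95). Il2ra, the high-affinity chain of the IL-2 receptor, rose by 1.03. Of 22 genes of amino acid transport and targets of the stress factor ATF4, 8 rose and 2 fell, 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.494 with an estimated correlation), with the serine synthesis enzyme Phgdh at 0.37 and the stress factor Ddit3 at -1.03. Of 19 glycolysis genes 5 rose and 14 did not pass (6 rose when adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.581 with an estimated correlation), led by the lactate transporter Slc16a1 (0.68) and hexokinase Hk2 (0.57). Mitochondrial transcripts, a marker set fixed beforehand for RNA quality, rose with these groups. Of 13, 8 passed, and 11 when adjusted over the list alone (camera adjusted p = 3.1e-05, adjusted p = 0.733 with an estimated correlation). Their share of reads was 2.73% and 2.94% in Dusp2KO CD44hi against 2.15% and 2.03% in WT CD44hi. A difference in RNA quality between the libraries was not separated from the genotype.

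Interferon response and quiescence genes were lower in Dusp2KO CD44hi cells. Of 30 type I interferon response genes, 19 fell and 11 did not pass, 1 higher and 20 lower when adjusted over the list alone (camera adjusted p = 6.6e-07, adjusted p = 0.494 with an estimated correlation). Oasl1, a member of the OAS family, was at -0.88, Rtp4 at -0.70 and Irf9, a subunit of the interferon-activated factor ISGF3, at -0.55. Of 23 genes of naive and quiescent T cells 12 fell and 3 rose, 3 higher and 14 lower when adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.462 with an estimated correlation), with the growth-inhibiting genes Pik3ip1 at -0.91 and Btg1 at -0.70. Of 11 inhibitory receptor genes 4 fell and 7 did not pass, also 4 when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.589 with an estimated correlation). These were Ctla4 (-0.86), the ectonucleotidase Nt5e (-0.87), Tigit (-0.48) and Cd200 (-0.47). Of 10 genes of the IL-4 and STAT6 response 5 fell, 6 when adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.494 with an estimated correlation), with Nfil3 at -0.57 and Gata3 at -0.37. Of 37 genes of oxidative phosphorylation 13 fell and 24 did not pass (17 fell when adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.589 with an estimated correlation). Their median was -0.19 in this comparison and 0.17 between the CD44lo libraries. Across all genes, differences correlated with gene length in opposite directions (Spearman rho = 0.27 in CD44hi and -0.33 in CD44lo).

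The other 8 gene lists did not pass in CD44hi. ERK feedback genes and MAP kinase phosphatases without Dusp2 had 2 of 13 members higher and 6 lower, 2 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.065), among them Dusp10 (-0.66) and the ERK pathway inhibitor Spry2 (-0.46). Virtual memory and CD8 memory genes had 3 of 23 higher and 6 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.191). The T-box factor Tbx21 was at 0.52, the NK receptor genes Klrd1 and Klrc1 at -0.98 and -0.45, and the survival gene Bcl2 at -0.42. P53 targets and apoptosis genes split into 5 higher and 6 lower of 20, 5 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.749), with the cell cycle inhibitor Cdkn1a at 1.23 and the pro-apoptotic Bcl2l11 at -1.05. Chemokine receptor and trafficking genes had 4 of 17 higher and 6 lower, 4 higher and 10 lower when adjusted over the list alone (camera adjusted p = 0.216), with the homing receptor Cxcr4 at -1.15.

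Common gamma chain and STAT5 genes had 3 of 17 higher and 4 lower, 3 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.930), and their median of -0.05 and mean of 0.06 had opposite signs. TNF receptor family and costimulation genes had 5 of 14 higher and 2 lower, 5 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.366). Cholesterol synthesis had 3 of 24 higher and 21 not past the threshold, also 3 higher when adjusted over the list alone (camera adjusted p = 0.216). The unfolded protein response had 1 of 20 higher and 1 lower, and only Sec61b, which was at -0.56, passed when adjusted over the list alone (camera adjusted p = 0.188).

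**Figure D2:**
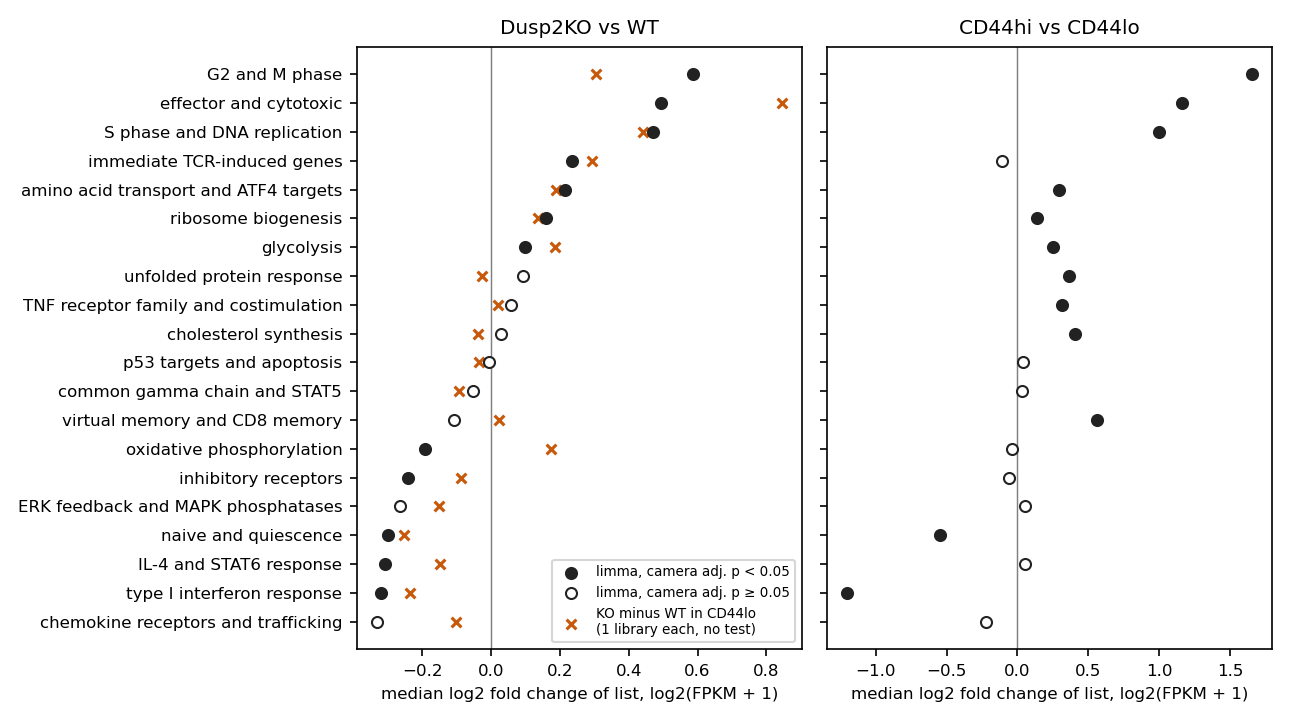
Median log2 fold change of each of the 20 gene lists (horizontal axes, log2(FPKM + 1) scale) for Dusp2KO against WT in CD44hi (left, circles) and for CD44hi against CD44lo adjusted for genotype (right), with filled circles for lists past the camera threshold and crosses for the untested difference between the single CD44lo libraries. The type I interferon list lay at -0.32 on the left and -1.20 on the right, and the S phase list at 0.47 and 1.00.

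The same genotype difference in CD44lo cells rests on 1 library each and was described without a test. Ifng was at 11.9 FPKM in WT and 77.7 FPKM in Dusp2KO, Ccl3 at 25.5 and 139 FPKM, Ccl4 at 120.4 and 628 FPKM, and Rrm2 at 2.44 and 9.25 FPKM. On the other side, Lgals3 was at 13.7 FPKM in WT and 0.0902 FPKM in Dusp2KO, and Ifi208 at 48.5 and 3.77 FPKM. Unlike in CD44hi, Kap and the short RNA Mir8091 were also lower, at -2.92 and -3.19 log2 units against 0.07 and 0.62. The median difference of the effector list was 0.84 on the log2 scale, at percentile 100 of 10000 random lists matched on size and mean expression. The S phase list (0.44) and the early TCR list (0.29) were also at percentile 100, the naive list (-0.25) at 0.01 and the interferon list (-0.24) at 0. Oxidative phosphorylation (0.17), which was lower in CD44hi, was at percentile 98.6, with 29 genes higher and 8 lower. These percentiles describe genes within a single pair of libraries and are not p-values. The random lists were not matched on gene length, with which the difference correlated across genes (Spearman rho = -0.33). Mitochondrial reads moved with these lists, at 3.79% in Dusp2KO CD44lo and 2.56% in WT CD44lo. The libraries differed 2-fold or more in 163 genes (77 higher and 86 lower in Dusp2KO), and in 323 (181 higher and 142 lower) with a pseudocount of 0.1.

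The CD44lo libraries enter the filter but not the CD44hi difference, so they give a separate direction for its genes. Of the 2586 genes called in CD44hi, 1736 (67.1%) differed in the same direction in CD44lo, against 56.6% of all genes tested. Of those with a 2-fold or larger difference it was 92 of 97 (94.8%), and 49 of 54 (90.7%) without chromosome 14. The differences in both fractions correlated across all genes tested with Pearson r = 0.42 and Spearman rho = 0.22. These shares and correlations describe genes of a single pair of CD44lo libraries, and genes are not independent replicates.

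**Figure D3:**
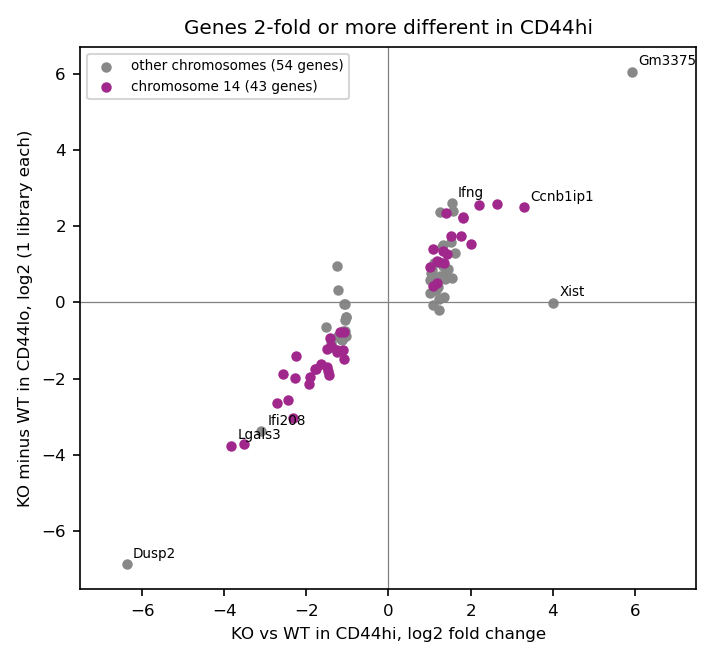
Log2 difference between Dusp2KO and WT in CD44hi (horizontal, 2 libraries per genotype) and in CD44lo (vertical, 1 library per genotype) for the 97 genes with a called 2-fold or larger difference in CD44hi, each point a gene, coloured by whether it lies on chromosome 14 (43 genes) or elsewhere (54 genes). Most points lie in the quadrants of equal sign (92 of 97), and Xist, at 4.02 in CD44hi, lies near 0 on the vertical axis.

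With both fractions in an additive model, the difference between 3 Dusp2KO and 3 WT libraries gave the genotype effect adjusted for the sorted fraction. The model assumes the same genotype effect in both fractions. It includes all libraries of the CD44hi comparison and is not independent of it. Effector genes were higher in Dusp2KO, with Ifng at 1.89, Ccl3 at 1.84, Ccl4 at 1.62, Il2 at 1.51, Lta at 1.35 and the granzyme inhibitor Serpinb9 at 1.10. In CD44hi, Ifng, Ccl3 and Ccl4 differed less (1.54, 1.56 and 1.25), and in the single CD44lo pair they differed more. They passed the interaction test (limma adjusted p = 0.033, 0.032 and 0.032), though not with the trend on gene length removed. Rrm2 (log2 fold change 1.53, SE 0.067, adjusted p = 5.6e-05) was higher as well. Lgals3 (log2 fold change -3.81, SE 0.084, adjusted p = 8.9e-07), Ifi208 (-3.19), Klf2 (-1.23) and Dusp1 (-1.11) were lower. Among 33 S phase genes 18 rose (28 when adjusted over the list alone; camera adjusted p = 9.3e-19, adjusted p = 0.051 with an estimated correlation), and among 21 G2 and M phase genes 10 (12 when adjusted over the list alone; camera adjusted p = 2.4e-08, adjusted p = 0.120 with an estimated correlation). Among 18 effector genes 10 rose and 1 fell, 12 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.342 with an estimated correlation). Among 30 interferon response genes 14 fell, 1 higher and 20 lower when adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.208 with an estimated correlation), with Mx1, an antiviral GTPase, at -0.61. Mitochondrial transcripts were higher as well, 9 of 13 passing and 11 when adjusted over the list alone (camera adjusted p = 6.2e-08, adjusted p = 0.299 with an estimated correlation).

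In this model 1008 genes passed, 507 higher and 501 lower. The count was 259 and 215 without Dusp2KO CD44hi replicate 1 or 2, 227 and 402 without WT CD44hi replicate 1 or 2, 2590 without the Dusp2KO CD44lo library and 2583 without the WT CD44lo library. Without a CD44lo library this genotype difference rests on the CD44hi libraries alone, so the counts without one are those of the CD44hi comparison. With all libraries the count was 318 with no filter, 468 with the replicate number as a block and 2168 as the mean of the contrasts within each fraction. It was 1558 with a trend on gene length removed (chosen after seeing the data) and 57 without the fraction in the model.

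CD44hi cells differed from CD44lo cells, adjusted for genotype, in effector, cell cycle and interferon genes. Beside the sorting marker Cd44 (4.88), Ifng (log2 fold change 3.43, SE 0.215, adjusted p = 7.7e-05) and the chemokines Ccl1 (3.42) and Ccl9 (2.95) were higher in CD44hi. So were Pclaf (2.79), which binds the replication clamp PCNA, Rrm2 (2.59), Ccna2 (2.54) and the cytokine RANKL gene Tnfsf11 (2.16). Genes lower in CD44hi were led by the interferon-induced Ifit1bl1 (-3.31), Ifit3b (-2.90) and Ifit3 (log2 fold change -2.80, SE 0.091, adjusted p = 7.7e-06), followed by the GTPase Gbp11 (-2.75), Klf2 (-2.39) and S1pr1 (-2.29), the receptor by which T cells leave lymph nodes. The Ifit3 level was 196 FPKM in WT CD44lo and 159.8 FPKM in Dusp2KO CD44lo, against 30.1 ± 2.29 FPKM in WT CD44hi and 19.9 ± 0.205 FPKM in Dusp2KO CD44hi. Ifit3 and Ifit3b are near-identical copies that can share reads.

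The S phase, G2 and M phase and naive lists were the only ones of the 120 list tests whose call held with an estimated correlation. That test also uses the residual degrees of freedom, 3 in this model, so lost calls are not a measure of correlation alone. For Dusp2KO against WT in CD44hi, the naive list had an estimated correlation of -0.0033. Its camera p still went from 0.0011 to 0.069, though the preset was 0.01. Other lists that passed there had higher estimates. These were 0.52 for oxidative phosphorylation, 0.47 for inhibitory receptors, 0.36 for the effector list and 0.30 for G2 and M phase. S phase (0.017) and ribosome biogenesis (0.0061) stayed near the preset. Correlation between members can thus account for part of the lost calls. Of 33 S phase genes 31 were higher in CD44hi (32 when adjusted over the list alone; camera adjusted p = 3.1e-19, adjusted p = 0.031 with an estimated correlation). Of 21 G2 and M phase genes 20 were higher, also 20 when adjusted over the list alone (camera adjusted p = 2.6e-16, adjusted p = 0.031 with an estimated correlation). Of 23 naive genes 15 were lower (16 when adjusted over the list alone; camera adjusted p = 2.7e-11, adjusted p = 0.031 with an estimated correlation), among them the IL-7 receptor Il7r (-1.24). All 30 interferon response genes were lower in CD44hi, under both adjustments (camera adjusted p = 1.3e-27, adjusted p = 0.057 with an estimated correlation). Of 18 effector genes 11 were higher, 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000196, adjusted p = 0.463 with an estimated correlation), with the cytokine Csf2 at 2.74, the chemokine Ccl5 at 1.82 and granzyme A gene Gzma at 1.83. Of 23 virtual memory genes 11 were higher and 3 lower, 11 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0084, adjusted p = 0.380 with an estimated correlation), with Klrc1 at 2.04 and the IL-18 receptor chain Il18rap at 1.52.

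Biosynthetic lists were higher in CD44hi too. Cholesterol synthesis had 15 of 24 genes higher (20 when adjusted over the list alone; camera adjusted p = 4.2e-06, adjusted p = 0.245 with an estimated correlation), with Idi1 at 0.80, and the unfolded protein response 14 of 20 (15 when adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.539 with an estimated correlation), with the disulfide isomerase Pdia6 at 0.72. Amino acid transport and ATF4 targets had 12 of 22 higher and 2 lower under both adjustments (camera adjusted p = 0.015, adjusted p = 0.245 with an estimated correlation), with asparagine synthetase Asns at 1.55. Glycolysis had 7 of 19 higher (10 when adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.310 with an estimated correlation). TNF receptor family genes had 6 of 14 higher (8 when adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.696 with an estimated correlation), with the costimulatory receptor Tnfrsf4 at 1.43. Ribosome biogenesis passed as a list (camera adjusted p = 0.018, adjusted p = 0.245 with an estimated correlation) with 4 of 27 genes higher, though not when adjusted over the list alone. That share was no larger than the 1610 of 9691 over all genes. The list median was 0.14, against 0.05 for all genes. Early TCR genes did not pass as a list (camera adjusted p = 0.107), though Nr4a1 (-1.31), Egr1 (-1.24) and Jun (-1.09) were lower in CD44hi. With these groups, mitochondrial transcripts were lower in CD44hi, 6 of 13 passing and 9 when adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.271 with an estimated correlation). CD8 T cell identity genes were lower too, 7 of 11 under both adjustments (camera adjusted p = 2.8e-05, adjusted p = 0.271 with an estimated correlation).

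Across all genes 2655 passed, 1610 higher and 1045 lower in CD44hi. The split depended on the scaling, with 1328 higher and 1281 lower with median-ratio scaling, 1368 and 1286 with quantile normalization, and 1803 and 801 with each library rescaled to a total of 1000000. It was 1597 and 1501 with the length trend removed, chosen after seeing the data. With the replicate number as a block 1601 genes passed. The count fell to 1665 and 1570 without Dusp2KO CD44hi replicate 1 or 2 and to 1617 without WT CD44hi replicate 1, was 4258 as the mean of the contrasts within each genotype, and was 1220 without genotype in the model.

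Within each genotype the fractions differed in many of the same genes. In WT, 2527 genes passed (1490 higher and 1037 lower in CD44hi; 1253 and 1318 with median-ratio scaling), with Ifng at 3.96, the chemokine receptor Cxcr3 at 2.16 and Klrc1 at 2.33. In Dusp2KO, 3888 passed (2285 higher and 1603 lower; 3154 and 969 with each library rescaled to a total of 1000000), with Ifng at 2.90, Mki67 at 3.28 and Klf2 at -2.82. That rescaling moved the median of all genes from 0.05 to 0.18. Both genotypes shared 1555 calls of the same direction, 904 higher and 651 lower in CD44hi against 351 and 172 for independent lists, and 83 calls of opposite direction. The 2 comparisons contrast no common library but share the variance estimate of each gene. Genes of small spread can thus be called in both, so the counts for independent lists may be too low a baseline. The Dusp2KO fractions differed in Xist, with 0 reads in CD44lo, and may come from different animals. The CD44hi pairs of both genotypes set the spread, and each lone CD44lo library was assumed to vary like them. Interferon response genes were lower in CD44hi in both, 28 of 30 in WT (29 when adjusted over the list alone; camera adjusted p = 7.2e-25, adjusted p = 0.204 with an estimated correlation) and 29 of 30 in Dusp2KO (30 when adjusted over the list alone; camera adjusted p = 4.2e-22, adjusted p = 0.228 with an estimated correlation). Marker sets moved with them. Mitochondrial transcripts were lower in CD44hi, 4 of 13 in WT under both adjustments (camera adjusted p = 0.00074, adjusted p = 0.702 with an estimated correlation) and 6 of 13 in Dusp2KO under both (camera adjusted p = 0.0011, adjusted p = 0.774 with an estimated correlation). CD8 T cell identity genes were lower too, 5 of 11 in WT (6 when adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.702 with an estimated correlation) and 9 of 11 in Dusp2KO (10 when adjusted over the list alone; camera adjusted p = 3.5e-05, adjusted p = 0.522 with an estimated correlation). The WT count was 3825 without WT CD44hi replicate 2 and 1170 with no filter. The Dusp2KO count was 2559 and 2524 without Dusp2KO CD44hi replicate 1 or 2 and 2085 with no filter.

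The interaction asked whether the step from CD44lo to CD44hi differed between genotypes. Some effector genes stepped up less in Dusp2KO than in WT, though not all of these calls held under other settings. Ifng was 3.96 log2 units higher in CD44hi than in CD44lo in WT and 2.90 in Dusp2KO (log2 fold change -1.06, SE 0.158, adjusted p = 0.033). Ccl4 stepped up by 1.31 in WT and 0.19 in Dusp2KO, Ccl3 by 1.86 and 1.02, Cxcr3 by 2.16 and 0.97, and the granzyme gene Gzmc by 1.62 and 0.41. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at -0.20 in WT and 0.94 in Dusp2KO. With the trend on gene length removed (chosen after seeing the data), Ifng (-0.81, adjusted p = 0.073), Ccl4 (-0.81, adjusted p = 0.065), Ccl3 (-0.54, adjusted p = 0.094), Cxcr3 (-0.97, adjusted p = 0.053) and Ndufa1 (-0.33, adjusted p = 0.159) kept a smaller negative difference and no longer passed, while Gzmc (-0.93, adjusted p = 0.025) and Cdkn1a (1.21, adjusted p = 0.036) did. With limma voom on recovered reads, also chosen after seeing the data, Ifng (adjusted p = 0.021), Ccl4 (0.0102), Ccl3 (0.022) and Cxcr3 (0.029) passed and Ndufa1 (0.0698) did not. Of 18 effector genes 5 passed in the main test, all with a smaller step in Dusp2KO, and 10 when adjusted over the list alone (camera adjusted p = 6.0e-05, adjusted p = 0.930 with an estimated correlation). Oxidative phosphorylation also passed as a list (camera adjusted p = 4.5e-07, adjusted p = 0.930 with an estimated correlation). Of its 37 genes 1 passed on its own, Ndufa1 (-0.66), and 19 were negative when adjusted over the list alone. Across all genes the interaction values correlated with gene length (Spearman rho = 0.48).

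In all, 409 genes passed, 265 positive and 144 negative, or 379 and 43 with each library rescaled to a total of 1000000, which moved the median of all genes to 0.13. The contrast rests on 1 CD44lo library per genotype, its values correlated with gene length across genes (Spearman rho = 0.48), and the count was 3046 and 1734 without WT CD44hi replicate 1 or 2 (the latter 821 positive and 913 negative), 184 with the length trend removed, 225 with reads thinned to equal depth, 117 without a variance trend and 39 with no filter. The removal of the length trend and the thinning were chosen after seeing the data. With the replicate number as a block the count was 1565. The Dusp2KO libraries of the 2 fractions differed in Xist and may come from different animals, which the contrast does not separate from the step.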

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

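The removal of the length trend, the thinning of reads, the question of a deviating CD44lo library, and every test on chromosome 14 and on Xist were chosen after the result was seen. Bounds on the counts after length removal and thinning were set before those counts, while the comparison of fold sizes after thinning, and of ratios on other chromosomes, were added after the values were seen. The split of the libraries by genotype was planned.

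For the genotype difference adjusted for fraction, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1008 genes, the highest other split called 1, and 1 split, the real one, reached the real count. The other splits mix the genotypes without genotype in the model, so its differences enter their spread. Low counts were likely for them in advance, and they decide nothing about the real split.

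A difference in the step from CD44lo to CD44hi between the genotypes drew attention for 409 genes, tested by the interaction. The difference was 4.02 log2 units for Xist, 3.81 for Mir8091, 2.27 for Psme2b, 2.07 for Ighj1 and 1.84 for Ankhd1. It was 1.15 for Cdkn1a, 0.87 for Tsr1, 0.82 for Pmaip1, 0.77 for Pola1, 0.76 for Utp20, 0.66 for Egr3 and 0.64 for Top2a. In the other direction it was -0.55 for Nfkbid, -0.66 for Ndufa1, -0.68 for Ly6c2, -0.84 for Ccl3, -1.06 for Ifng and -1.12 for Ccl4. It was -1.19 for Cxcr3, -1.21 for Gzmc, -1.21 for Snora41, -1.39 for Snord34 and -1.41 for H3c1. Mir8091, Snora41 and Snord34 are short RNAs whose values in such libraries are uncertain, and Psme2b and Ighj1 can share reads with near-identical or neighbouring genes.

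Gene length is a candidate explanation for a large part of the 409 interaction calls, since their values correlated with length (Spearman rho = 0.48 across genes) and removal of the trend left 184 calls, 156 of them among the 409, with the median size of the 409 going from 0.82 to 0.61 (median SE 0.136 and 0.122). The lower depth of the Dusp2KO CD44lo library cannot be told apart from other sources, because thinning left 225 calls, under the bound set beforehand for a depth effect, but the median size hardly moved (0.82 and 0.81) while the median SE went from 0.136 to 0.147, which is a loss of precision. Whether 1 CD44lo library deviated from its group cannot be told apart either, with 1 CD44lo library per genotype. With the trend removed, H3c1 (adjusted p = 0.017), Gzmc (0.025) and Cdkn1a (0.036) still passed in limma, while Ifng (-0.81, adjusted p = 0.073), Ccl3 (-0.54, 0.094), Ccl4 (-0.81, 0.065) and Cxcr3 (-0.97, 0.053) kept a smaller negative difference and did not. The Dusp2KO CD44hi and CD44lo libraries also differed in Xist (15308 and 14690 reads against 0) and may come from different animals. An effect of Dusp2 loss on the step remains open and was not separated from these.

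Of the 97 genes with a 2-fold or larger genotype difference in CD44hi, 43 lie on chromosome 14, 33 of them T cell receptor segments and 10 others (Lgals3, Ccnb1ip1, Tmem254a, Sall2, Snord8, Gm43305, Psmb5, Ppp1r3e, Pbk and Egr3, of which those outside the rule for named genes were chosen after their values were seen). Receptor segments do not make up all of the cluster, since 10 of its genes are others. Of the other 332 genes on that chromosome 3.01% differed as much, against 0.575% of 9224 genes elsewhere (one-sided Fisher exact p = 5.55e-05). The chromosome was chosen for this cluster and neighbouring genes are not independent, so this p-value may overstate the excess outside the segments. Gene length does not account for the cluster, with 45 such genes after removal of the trend. A stretch of chromosome 14 from another mouse strain, apart from Dusp2 on chromosome 2, is a candidate explanation, since the CD44lo differences of the 10 genes had a median of 1.02 times the CD44hi ones, against 0.636 for such genes on other chromosomes without Dusp2. It cannot be told apart from a genotype effect shared by both fractions, because all Dusp2KO libraries are set against all WT libraries. All 10 kept their direction in CD44lo, while Egr3 was smaller there (0.44 against 1.10 in CD44hi) and passed the interaction in the main test. An effect of Dusp2 loss on the chromosome 14 genes remains open and was not tested.

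Xist had 15308 and 14690 reads in the Dusp2KO CD44hi libraries, 0 in the Dusp2KO CD44lo library and 5, 5 and 2 in the WT libraries. Depth does not account for the 0, since 6536 reads would be expected there at the CD44hi level, and a swap of that library with a WT library is argued against by its Dusp2, at 0 times the lowest WT level. Cells of female mice among those of the Dusp2KO CD44hi libraries are a candidate explanation, as 3 of 4 Y-linked genes were lower there than in every other library, Eif2s3y at 0.709, Kdm5d at 0.809 and Ddx3y at 0.844 of the mean of the others, though Ddx3y, at 10.5 and 10.3 FPKM, was close to the 10.6 FPKM of WT CD44hi replicate 2 and nearer to it than that was to replicate 1 (13.6 FPKM). It cannot be told apart from other sources, because Uty was not lower there and Dusp2KO CD44hi and CD44lo libraries may come from different animals. No biological explanation beyond sex was tested.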

How the results depend on the processing

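The alternatives on recovered reads, gene length, thinned reads and chromosome 14 were chosen after seeing the data. Where the cause is not given, the cause was not tested. With no filter on low values, which adds genes near 0, the genes past the threshold numbered 2 for Dusp2KO against WT in CD44hi (2586), 318 adjusted for fraction (1008), 1170 for CD44hi against CD44lo in WT (2527), 2085 in Dusp2KO (3888) and 39 for the interaction (409). Averaging the contrasts within groups gave 4258 for CD44hi against CD44lo adjusted for genotype (2655) and 2168 for the adjusted genotype difference. Without the other factor these were 1220 and 57, where its differences enter the spread. Removing the length trend gave 1558 for the adjusted genotype difference and 184 for the interaction, and moved the same-sign share from 67.1% to 74.3%. The interaction count was 117 without the variance trend and 225 with thinned reads. With an estimated correlation, where the test also uses the 2 or 3 residual degrees of freedom, 3 of the 59 list calls held. With the length trend removed, 115 of 120 list results kept their side of the threshold, 4 gained the call and 1 lost it. A pseudocount of 0.1 gave 323 genes with a 2-fold difference between the CD44lo libraries (163).

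Leaving out each library in turn gave 1088 to 4092 genes for Dusp2KO against WT in CD44hi, 215 to 2590 adjusted for fraction, 1570 to 3886 for CD44hi against CD44lo adjusted for genotype, 2171 to 3825 in WT, 2524 to 5515 in Dusp2KO and 346 to 3046 for the interaction. A fit that leaves 1 library in an arm assumes that it varies like the other groups. Without a CD44lo library the adjusted genotype difference rests on CD44hi alone, and the adjusted fraction difference on the genotype that keeps both fractions. The upper ends of the ranges of both adjusted comparisons come from such fits. The contrasts of the fractions within a genotype and the interaction cannot be estimated without the CD44lo library they use. Same-numbered CD44hi libraries of the genotypes did not deviate together (correlation 0.022 across genes). With a single pair per genotype this does not exclude that the numbers pair them. With the replicate number as a block the counts were 1601 for CD44hi against CD44lo adjusted for genotype, 468 for the adjusted genotype difference and 1565 for the interaction, and the other 3 counts stayed within 1.5 times. Of 10826 values of 541 named gene results under the alternatives, 10002 kept their direction and side of the threshold, 563 lost the call, 260 gained it and 1 reversed, Dusp2, CD44hi vs CD44lo in KO, under quantile normalization (-0.27 from 0.02), where all values are near 0. Of the lost calls 189 came with no filter on low values, most of all in Dusp2KO against WT in CD44hi. Low depth limits genes near the floor of 3 reads, which is highest in the Dusp2KO CD44lo library.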

Other observations

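Markers of other cell types, fixed before the data were examined, stayed low in all 6 libraries, with some exceptions. The 8 B cell genes in the table summed to between 125 and 153 FPKM, nearly all of it Ighm (up to 139.6 FPKM) and Cd79b, while Cd79a reached no more than 0.379 FPKM. Cd79b was at 22.4 and 24.5 FPKM in Dusp2KO CD44hi, 12.2 and 9.88 FPKM in WT CD44hi, 11.2 FPKM in Dusp2KO CD44lo and 6.92 FPKM in WT CD44lo. Of the B cell genes 3 were tested and 1 was higher in Dusp2KO CD44hi (camera adjusted p = 0.512). The sets of 2 tested dendritic cell and 2 tested myeloid genes did not pass (camera adjusted p = 0.841 and 0.512). Myeloid genes summed to at most 5.11 FPKM, NK and gamma delta T cell genes to less than that in every library, dendritic cell and MHC class II genes to 7.75, and red cell genes to 0.375. Stromal and endothelial genes summed to 14.4 FPKM in WT CD44lo, of which Pecam1 gave 14.3 FPKM. The CD4 and regulatory T cell sum was nearly all Il2ra, with Foxp3 at no more than 0.193 FPKM.

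Zbtb46, a transcription factor of dendritic cells in the marker list, was at 1.86 and 1.82 FPKM in Dusp2KO CD44hi and at 0.619 and 0.653 FPKM in WT CD44hi. Heat stress genes had 4 of 7 members higher in Dusp2KO CD44hi (camera adjusted p = 0.078), with Hspa8 at 1461 and 1476 FPKM against 1038 and 1150.0 FPKM. CD8 T cell identity genes had 1 of 11 higher and 6 lower in Dusp2KO CD44hi (camera adjusted p = 0.078), with Cd3e at 51.7 and 53.5 FPKM against 88.6 and 76.9 FPKM.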
